A study of Homo sapiens with 12 samples.

How the data were processed

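Human pulmonary artery endothelial cells, the cells that line the vessels carrying blood from the heart to the lungs, had been transfected with siRNA for 72 hours, per the labels' protocols. Total RNA was labelled with Cy3 and hybridised to an Illumina microRNA BeadChip, on which bead-bound probes report the amount of each microRNA. The 12 arrays fell into 4 groups of 3, which received control siRNA, apelin siRNA, APJ siRNA, or apelin siRNA and APJ siRNA together. The labels call the control a high-GC siRNA, and it was the 1 control siRNA of the study. All 12 arrays were sections of 1 chip. The control and APJ siRNA arrays alternated along sections A to F, and the apelin and double siRNA arrays alternated along sections G to L. Apelin siRNA and the side of the chip therefore cannot be told apart, whereas APJ siRNA against control siRNA was compared within 1 side. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Transcripts of the targeted genes were not measured by this assay, so the depth of each knockdown was not checked here.

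The deposited table gives a mean bead intensity and a detection p-value per probe and array, exported from GenomeStudio by the authors per the submitters' processing notes and the file header, with no version given in the sources used here. The header calls the table not normalized, yet every array had the same mean intensity over the 1145 probes, 3474, so the deposited values had been scaled to a common mean. Background had not been subtracted. The detection p-value sets each deposited probe intensity against background on the same array. A second deposited table of intensities was a straight line of the first for each array, with a largest residual of 0.1, slopes of 0.990 to 1.01 and intercepts of -384 to -312. That table was on a linear scale, had a mean of 3128 per array, array medians of 159.8 to 375 and values below 0, as a subtraction of background followed by rescaling would give. It was uncentred by probe and ran in the same direction as the first table.

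Intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3, which estimates background from the detection p-values, adds an offset of 16, applies quantile normalization between arrays and takes log2. A probe was called detected where its detection p-value was under 0.01. Probes detected on at least 3 of the 12 arrays were tested, which kept 729 of 1145. A mean per group was fitted to all 12 arrays with lmFit, so that the 4 groups shared 1 estimate of the spread, and eBayes gave moderated 2-sided tests with Benjamini-Hochberg adjustment within each comparison at 0.05. The fit had 8 residual and 1.61 prior degrees of freedom. After quantile normalization 1 probe, the brightest on every array, had no spread. Comparisons were each knockdown against control siRNA, apelin siRNA against APJ siRNA, the interaction of both siRNAs, and each siRNA averaged over the presence of the other. The double knockdown was also set against each single knockdown. "Rose" and "fell" are used for probes past the threshold, with the group named first against the group named next.

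Where every array of a group left a probe undetected, its level there is only a bound. The brighter mean was then set against the mean, over the arrays of the dim group, of the higher of the lowest detected intensity and the probe's own value, on the log2 scale, and the ratio is printed as at least that fold. Fitted log2 changes of named probes between 2 groups are printed with that bound. An interaction has no such bound, and undetected groups are named beside it.

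The tables pair no probe with a microRNA name, and the gene table used here matched none of the probe IDs, so probes are given by ID. The 19 lists of microRNAs with 232 members that had been written before the data were examined, among them microRNA clusters and markers of other cell types, could not be matched to probes and were not tested. The rule for naming, also written before the data were examined, was the largest rises and falls past the threshold, limited to 2 probes per direction where no name is known. Probes named outside it were chosen after their values were seen, which is said where they appear. Sets of probes called in 1 comparison were tested in a comparison that shares no array with it, using camera with a preset correlation of 0.01 and again with an estimated correlation.

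Comparisons with the same control arrays share those arrays' chance values. Arrays of all groups, the control group included, were therefore simulated 100 times as unchanged, drawn around each probe's control mean. Correlations, covariances and shared calls were computed again from these draws. The measured control arrays were not the reference in them, so the chance values of those arrays themselves were not tested. The control arrays were too few to be split. No array pair within a group held identical values, and the smallest median difference between arrays of a group was 0.14 (log2).

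The fit was tested on data simulated for apelin siRNA against control siRNA over 1145 probes in 5 runs. It recovered 13.2% of probes changed 1.5-fold, 36.8% of those changed 2-fold and 73.1% of those changed 4-fold. Of 230 calls, 23 fell on unchanged probes, or 10%. Changes of 4-fold and less can thus be missed at 3 arrays per group, and the number of arrays limits the precision.

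Alternatives covered the background correction, the normalization between arrays, the second table with values under 50 raised to 50, the filter on dim probes, the arrays in the fit, the estimate of the spread, the replicate number as a block, the section along the chip as a covariate, and leaving out each array in turn. Weights per siRNA group, and a fit without the probes undetected on all 3 control arrays, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.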

Results

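MicroRNAs were profiled in human pulmonary artery endothelial cells after knockdown of apelin, a secreted peptide ligand, of APJ, its G protein-coupled receptor, or of both. The question, as the title of the series puts it, was which microRNAs are targets of the ligand and its receptor. Each of the 4 siRNA groups had 3 arrays of 1145 probes. The number of probes detected per array was 633 ± 15.9 (SD, n = 3) with control siRNA, 653 ± 22.9 with apelin siRNA, 670.0 ± 58.9 with APJ siRNA and 638 ± 30.9 with both. The share detected ranged from 53.3% to 64.5% over the 12 arrays, and 488 probes were detected on all of them. Probe identities were not analysed here beyond the array's own IDs.

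The control arrays were more alike than the knockdown arrays. Within the control group, arrays correlated at 0.984 to 0.993 across probes, against 0.922 to 0.970 for apelin siRNA, 0.922 to 0.925 for APJ siRNA and 0.938 to 0.977 for both. Of the 9 knockdown arrays, 3 correlated best with an array of their own group. The groups are taken as labelled, and an exchange of labels or extracts was not tested, since the knocked-down transcripts were not measured. The median SD of a probe between arrays of a group was 0.16 (log2) with control siRNA, 0.32 with apelin siRNA, 0.47 with APJ siRNA and 0.30 with both. Of the 729 probes tested, 65 were undetected on all 3 control arrays. The filter kept only probes detected on at least 3 arrays, so these 65 had to be detected on at least 3 knockdown arrays. They were bright on some knockdown arrays and dim on others of the same group. APJ siRNA arrays 1, 2 and 3 detected 49, 23 and 52 of them, apelin siRNA arrays 6, 43 and 48, and double knockdown arrays 24, 14 and 5.

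**Figure D1:**
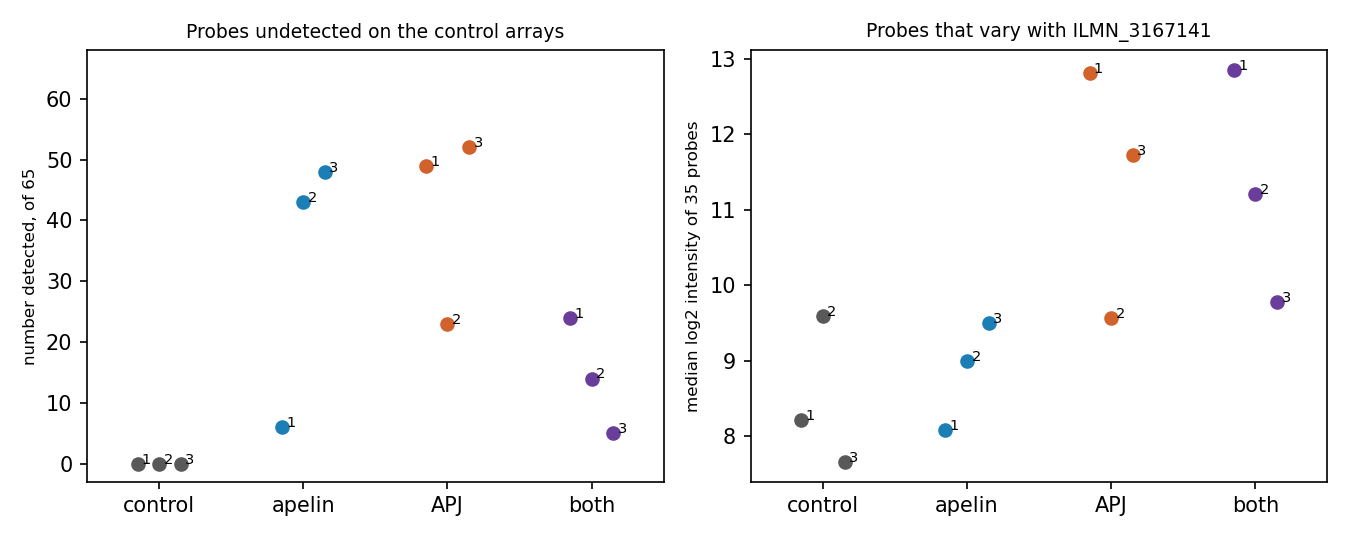
Left, the number of the 65 probes undetected on every control array that each array detected. Right, the median log2 intensity of 35 probes that varied with ILMN_3167141, for each array. Points are single arrays with their replicate number, grouped by siRNA on the horizontal axis. Knockdown arrays of 1 group differ widely, from 6 to 48 probes with apelin siRNA.

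With apelin siRNA, 8 probes rose and 20 fell against control siRNA, in a comparison across the sides of the chip. The largest rise was that of ILMN_3167951, from 8.13 ± 0.23 (log2, SD, n = 3) to 11.25 ± 0.33. This was a change of 3.12 (SE 0.48), or 8.68-fold, with a limma adjusted p of 0.00609. ILMN_3168555 rose by 1.57 (SE 0.36, adjusted p = 0.0418). ILMN_3167414 fell by 2.28 (SE 0.35, adjusted p = 0.00609), from 10.65 ± 0.04 to 8.37 ± 0.71. ILMN_3168500 fell by 2.24 (adjusted p = 0.0418) and was undetected on all 3 apelin siRNA arrays, which makes it at least 1.39-fold lower. For each of these 4 probes, all 3 knockdown arrays lay beyond every control array. Chance gives this in 10% of comparisons of 3 against 3, but these probes were chosen by their change, which favours such a separation. At an unadjusted p under 0.05 the count was 117. The calls of ILMN_3167951 and ILMN_3167414 held without any single array, whereas those of ILMN_3168555 and ILMN_3168500 were lost without 9 and 8 of the 12 arrays. The split of 8 and 20 became 11 and 17 with median scaling and 12 and 14 in the second deposited table. The count of 28 became 1 with the section along the chip as a covariate and 44 with only the compared groups in the fit. It was 75 without apelin siRNA array 1, 11 without array 2 and 16 without array 3, and 11, 12 and 10 without control arrays 1, 2 and 3.

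With APJ siRNA, 18 probes rose and 49 fell against control siRNA, in a comparison of arrays that alternated along sections A to F. ILMN_3167874 fell by 3.00 (SE 0.45, adjusted p = 0.00495), from 9.29 ± 0.08 to 6.28 ± 0.79, and was detected on 1 of the 3 APJ siRNA arrays. ILMN_3168073 fell by 2.66 (SE 0.71, adjusted p = 0.0463), from 12.48 ± 0.06 to 9.82 ± 1.68. Both named rises were undetected on the control arrays. ILMN_3168669 rose by a fitted 3.17 (adjusted p = 0.0305), at least 2.43-fold, and ILMN_3166999 by a fitted 2.39 (adjusted p = 0.0455), at least 2.14-fold. For these 4 probes too, all 3 APJ siRNA arrays lay beyond every control array, with the same limit from the choice of probes. In all, 5 of the 18 rises belonged to the 65 probes undetected on the control arrays, which APJ siRNA arrays detected in very different numbers. The median over all 729 probes was -0.18, and 274 probes had an unadjusted p under 0.05. The call of ILMN_3167874 held without any single array, those of ILMN_3168669, ILMN_3166999 and ILMN_3168073 were lost without 4, 8 and 10 of the 12 arrays. The split of 18 and 49 became 28 and 29 with cyclic loess, which moved the median of all probes to 0.08, and 21 and 32 in the second deposited table. The count of 67 became 31 with the section as a covariate, 19 with only the compared groups and 102 with a trended, robust estimate of the spread. It was 188 without APJ siRNA array 2, 15 without array 3, 40 without apelin siRNA array 2, and 11, 12 and 13 without control arrays 1, 2 and 3.

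With both siRNAs, 6 probes rose and 22 fell against control siRNA, again across the sides of the chip. ILMN_3167951 again had the largest rise, 4.11 (SE 0.48, adjusted p = 0.00145), or 17.2-fold, to 12.24 ± 1.07. ILMN_3168575 rose by a fitted 2.01 (adjusted p = 0.044) from a level undetected on the control arrays, at least 2.17-fold. ILMN_3167175 fell by 2.45 (SE 0.21, adjusted p = 0.000326), from 12.77 ± 0.05 to 10.31 ± 0.34. ILMN_3167874 fell by 2.41 (SE 0.45, adjusted p = 0.0192) and was detected on 1 of 3 double knockdown arrays. At an unadjusted p under 0.05 the count was 115. The calls of ILMN_3167951 and ILMN_3167175 held without any single array, and those of ILMN_3168575 and ILMN_3167874 were lost without 9 and 5 of the 12. The count of 28 became 4 with the section as a covariate. It was 10 without double knockdown array 1, 17 without apelin siRNA array 2, and 7, 7 and 8 without control arrays 1, 2 and 3.

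**Figure D2:**
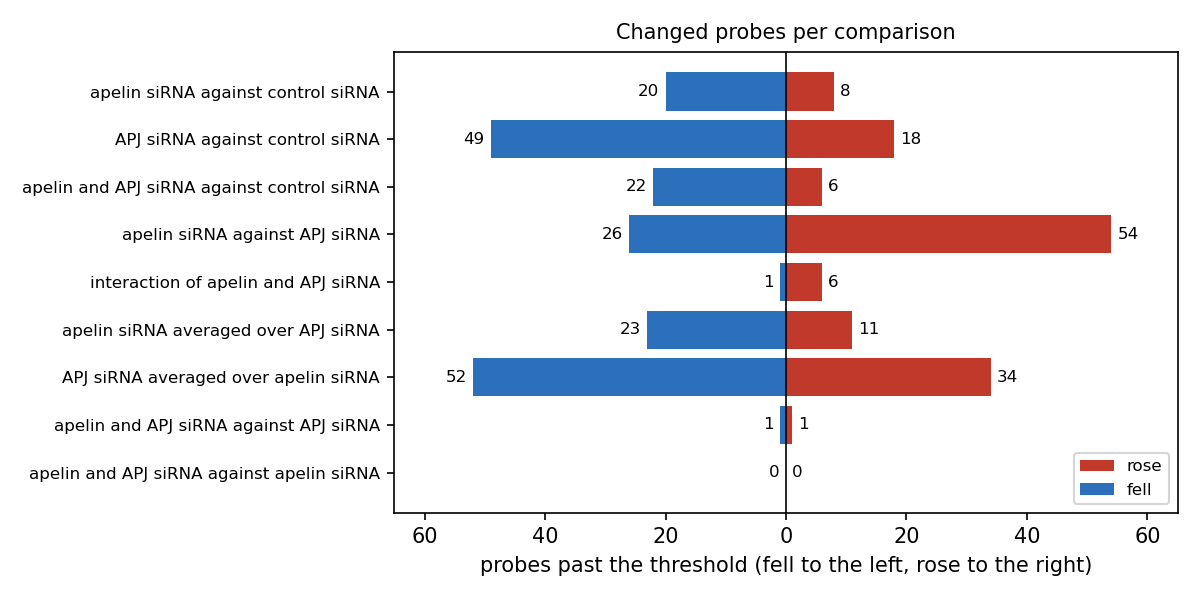
Number of probes past an adjusted p of 0.05 in each comparison, of 729 tested. Bars to the right count probes that rose and bars to the left probes that fell, the group named first against the group named next. Falls outnumber rises in the 3 comparisons with control siRNA, 20 to 8, 49 to 18 and 22 to 6.

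The 3 comparisons with control siRNA shared 10 calls, all of probes that changed in the same direction in each. Of these, 9 fell, namely ILMN_3167074, ILMN_3167175, ILMN_3167414, ILMN_3167801, ILMN_3168187, ILMN_3168216, ILMN_3168265, ILMN_3168273 and ILMN_3168884, and ILMN_3168694 rose. Most of these were named after their values were seen. Their changes ranged in size from 0.54 to 2.62 (log2), and in all 30 of the comparisons the knockdown arrays did not overlap the control arrays, which a choice by calls favours. ILMN_3167801 was undetected on all 9 knockdown arrays. None of 100 simulations of unchanged groups, with probes drawn independently, gave a probe called in all 3. Between apelin and APJ siRNA the falls shared 10 probes where independent lists would share 1.34, and between apelin siRNA and the double knockdown 13 where they would share 0.604. APJ siRNA and the double knockdown shared 14, against 1.48. Part of this excess may come from the shared control arrays, which could not be split. With the section as a covariate the 10 became 1, ILMN_3167801. Of the 10, 4 remained without control array 1, 2 or 3 or double knockdown array 1, 5 without APJ siRNA array 3 or apelin siRNA array 2, and 6 without APJ siRNA array 1.

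**Figure D3:**
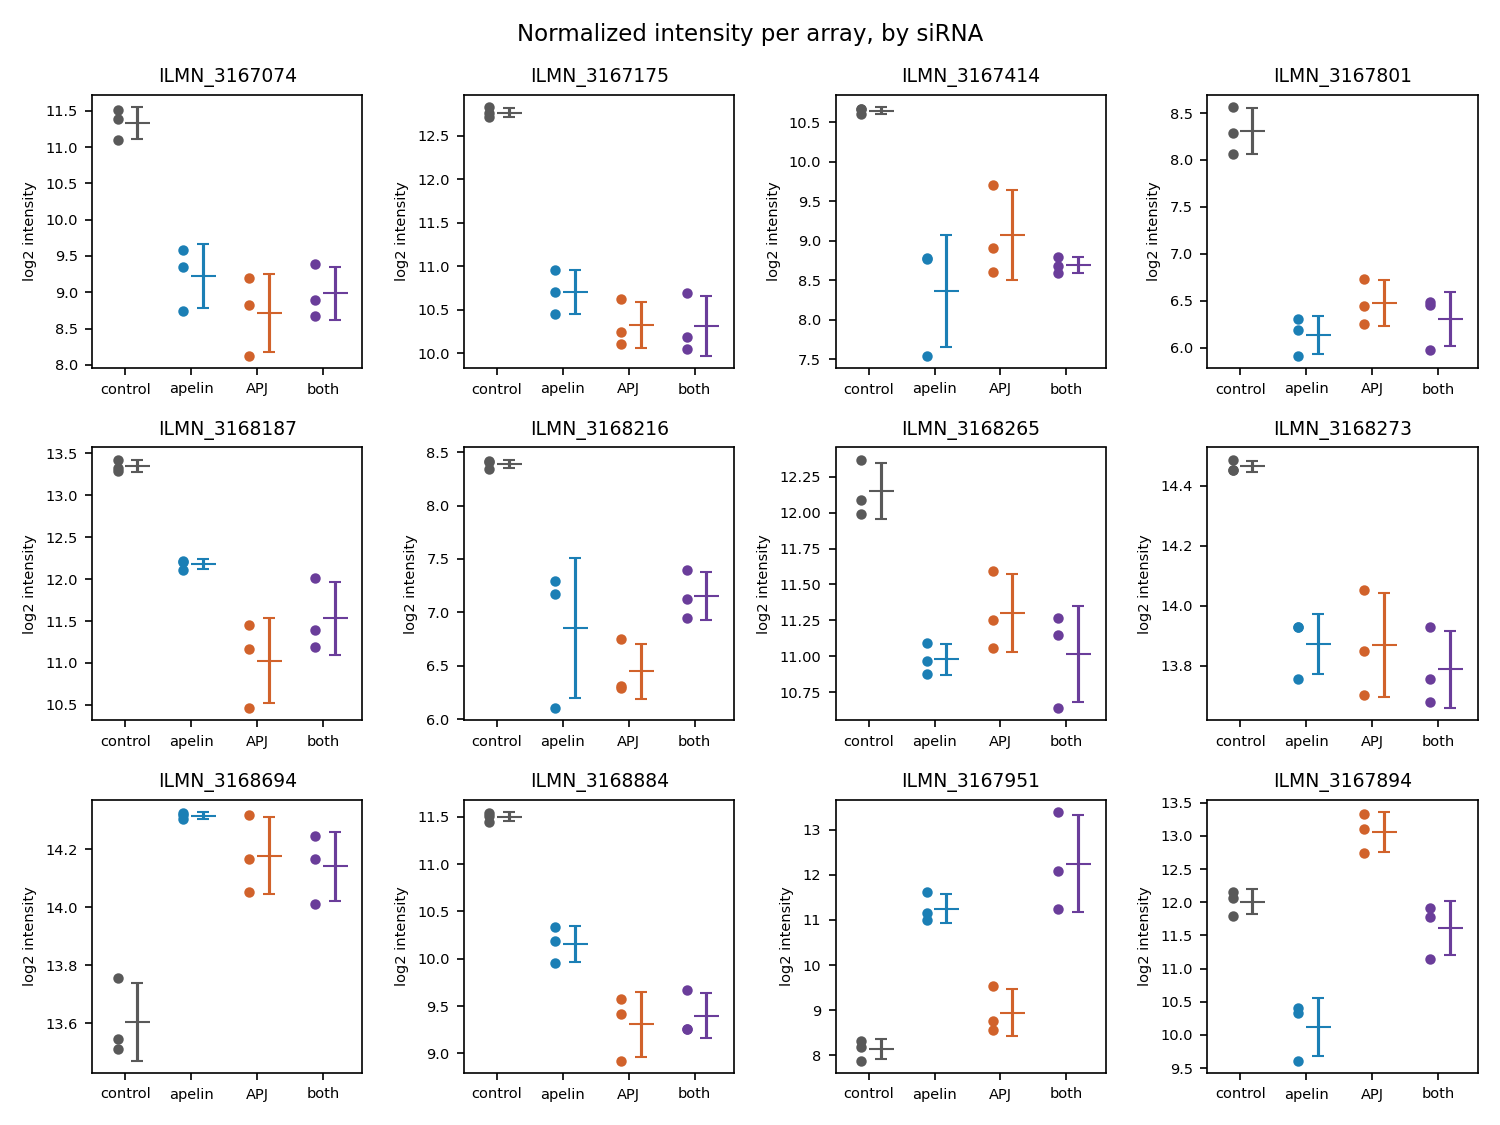
Normalized log2 intensity on each array for the 10 probes called in all 3 comparisons with control siRNA, and for ILMN_3167951 and ILMN_3167894. Points are arrays, horizontal bars the mean of 3 arrays and whiskers 1 SD, and vertical scales differ between panels. The 3 knockdown groups lie to 1 side of the control arrays in the first 10 panels.

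Across all 729 probes the changes with apelin siRNA and with APJ siRNA correlated at r = 0.558, where simulated unchanged groups gave 0.172 and at most 0.352. The covariance was 0.391, against 0.0292 simulated. APJ siRNA and the double knockdown correlated at 0.645, with 0.198 simulated and at most 0.344, and the covariance was 0.487 against 0.031. Apelin siRNA and the double knockdown correlated at 0.339, with 0.226 simulated and at most 0.365, and the covariance was 0.174 against 0.0296. Among the 488 probes detected on all arrays, r was 0.292 for apelin and APJ siRNA, within the simulated values of at most 0.401. It was 0.723 for APJ siRNA and the double knockdown and 0.523 for apelin siRNA and the double knockdown, above the simulated maxima of 0.442 and 0.465. Probes are not independent replicates, so these values describe these arrays. The simulations drew probes independently, so their ranges may be too narrow. Comparisons that share no array gave r = -0.404 for apelin siRNA without and with APJ siRNA, where simulated values ran from -0.216 to 0.131. They gave 0.114 for APJ siRNA without and with apelin siRNA, within simulated values of -0.148 to 0.188. Among the 488 always-detected probes these became 0.237 and 0.577, above simulated maxima of 0.194 and 0.239. The 0.237 cannot separate apelin siRNA from the side of the chip, since both comparisons set sections G to L against A to F.

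**Figure D4:**
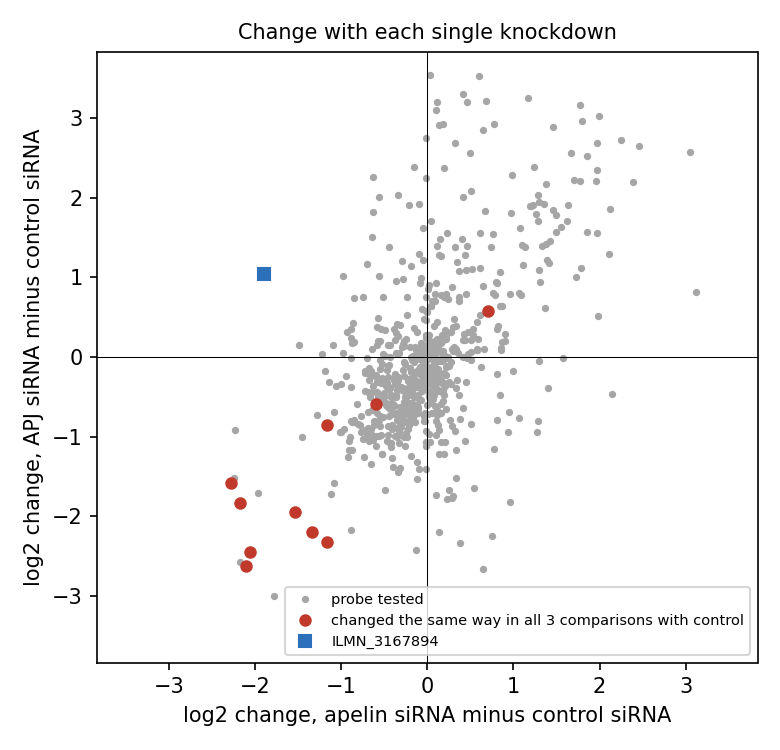
Log2 change with apelin siRNA (horizontal axis) and with APJ siRNA (vertical axis) against control siRNA, for each of 729 probes. Red points are the 10 probes called the same way in all 3 comparisons with control, and the blue square is ILMN_3167894, at -1.89 and 1.05.

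The probes called with apelin siRNA were looked up in the double knockdown against APJ siRNA, which uses none of the same arrays. Both comparisons set sections G to L against A to F, so a shared sign cannot separate apelin siRNA from the side of the chip. Of the 8 rises, 6 had the same sign (camera adjusted p = 0.00323, and adjusted p = 0.05 with an estimated correlation). Of the 20 falls, 15 did (adjusted p = 0.00323, and adjusted p = 0.336 with an estimated correlation). ILMN_3167951 rose by 3.29 (SE 0.48, adjusted p = 0.0183) and ILMN_3168339 fell by a fitted 2.08 (SE 0.27, adjusted p = 0.0153), at least 1.23-fold, and these were the 2 calls of this comparison, with 190 probes at an unadjusted p under 0.05. ILMN_3168339 was detected on all 3 APJ siRNA arrays and on no array of the other groups. Of the 49 falls with APJ siRNA, 40 had the same sign in the double knockdown against apelin siRNA (camera adjusted p = 0.000592, and adjusted p = 0.392 with an estimated correlation). Of the 18 rises, 9 did (adjusted p = 0.858, and adjusted p = 0.905 with an estimated correlation). No probe was called by limma between the double knockdown and apelin siRNA, where 19.6% of the 729 had an unadjusted p under 0.05.

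Set directly against each other, apelin siRNA was higher than APJ siRNA for 54 probes and lower for 26. This comparison set sections G to L against A to F, so the siRNAs and the side of the chip cannot be told apart. ILMN_3168073 was higher by 3.31 (SE 0.71, adjusted p = 0.0227) and ILMN_3168708 by a fitted 3.00 (SE 0.74, adjusted p = 0.0339), which rests on background levels on APJ siRNA arrays 2 and 3, where it was undetected. ILMN_3167894 was lower with apelin siRNA, at 10.12 ± 0.44 against 13.06 ± 0.30, a change of -2.94 (SE 0.27, adjusted p = 0.000806). It was the 1 probe called in opposite directions against control siRNA, where it fell by 1.89 with apelin siRNA (adjusted p = 0.00589) and rose by 1.05 with APJ siRNA (adjusted p = 0.0455). Its fall was measured across the sides of the chip and its rise within 1 side. ILMN_3167194 was lower by a fitted change of -2.14 (adjusted p = 0.0485) and undetected on the apelin siRNA arrays, at least 2.31-fold lower. The call of ILMN_3167894 held without any single array, and those of ILMN_3168073, ILMN_3168708 and ILMN_3167194 were lost without 4, 8 and 9 of the 12. The split of 54 and 26 became 42 and 40 with cyclic loess, and the count of 80 became 7 with the section as a covariate and 2 with only the compared groups. It was 33, 23 and 45 without apelin siRNA arrays 1, 2 and 3, 37 without APJ siRNA array 3, and 48, 50 and 46 without control arrays 1, 2 and 3. Weights per siRNA group gave 38. The shared spread includes the control arrays, whose median probe SD was 0.16, against 0.32 with apelin siRNA and 0.47 with APJ siRNA. The count of 80 may therefore be too high.

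Whether the response to apelin siRNA differed with and without APJ siRNA was tested by the interaction, which was called for 7 probes, 6 positive and 1 negative. Of these, 3 were detected on all 12 arrays, namely ILMN_3167074, ILMN_3167175 and ILMN_3168884. The other 4 lay at background on some arrays. Among them, ILMN_3167801 was undetected on all 9 knockdown arrays and ILMN_3168122 on all 3 APJ siRNA arrays, both named after their values were seen. A differing response is not shown for ILMN_3167801, ILMN_3168216 and ILMN_3168339, whose levels were at background where they would have to differ. The interaction was 2.38 (SE 0.45, adjusted p = 0.0425) for ILMN_3167074 and 2.24 (SE 0.41, adjusted p = 0.0425) for ILMN_3168216, both of which had fallen in each knockdown group. ILMN_3168216 was detected on 1 of 3 arrays in each of those groups. The fitted interaction was -2.58 (SE 0.38, adjusted p = 0.0148) for ILMN_3168339, which was undetected on every array of 3 of the 4 groups, so this value rests on background levels and its size is not measured. These calls were lost without 9, 8 and 5 of the 12 arrays. Of the 7 probes, 5 were among the 10 called in all 3 comparisons with control siRNA. At an unadjusted p under 0.05 the count was 184. The split of 6 and 1 became 7 and 30 with median scaling, 15 and 16 with cyclic loess and 1 and 3 in the second deposited table. The count was 122 without apelin siRNA array 1, 51 without APJ siRNA array 1, 4 without apelin siRNA array 2 or 3 or APJ siRNA array 3, 2 without double knockdown array 1, and 0 without control array 1, 2 or 3 or double knockdown array 3.

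Averaged over APJ siRNA, apelin siRNA raised 11 probes and lowered 23 in 6 arrays on sections G to L against 6 on sections A to F. ILMN_3167951 rose by 3.21 (SE 0.34, adjusted p = 0.00245) and ILMN_3168891 by 1.35 (SE 0.29, adjusted p = 0.0316). ILMN_3167894 fell by 1.67 (SE 0.19, adjusted p = 0.00279) and ILMN_3167414 by 1.33 (SE 0.25, adjusted p = 0.0156). The split of 11 and 23 became 18 and 21 in the second deposited table, and the count of 34 became 0 with the section as a covariate and 62 with cyclic loess. It was 20 without apelin siRNA array 2, 56 without APJ siRNA array 1, and 15, 21 and 18 without control arrays 1, 2 and 3. The call of ILMN_3168891 was lost without 10 of the 12 arrays and that of ILMN_3167414 without 1, and the other 2 named calls held without any single array.

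Averaged over apelin siRNA, APJ siRNA raised 34 probes and lowered 52. The largest rises were those of ILMN_3167141, 3.46 (SE 0.86, adjusted p = 0.0395), and ILMN_3167955, 3.22 (SE 0.83, adjusted p = 0.0421). ILMN_3167141 was detected on 1 of 3 control and 2 of 3 apelin siRNA arrays and ILMN_3167955 on 2 of 3 control arrays, so these fitted changes rest in part on background levels. ILMN_3168708, detected on 1 of 3 APJ siRNA arrays, fell by a fitted 1.93 (SE 0.53, adjusted p = 0.0448) and ILMN_3168073 by 1.88 (SE 0.50, adjusted p = 0.0433). ILMN_3167141 lay at 8.01 ± 1.31 with control siRNA and 8.05 ± 1.07 with apelin siRNA, and at 11.55 ± 1.99 with APJ siRNA and 11.43 ± 1.95 with both. It varied together with 34 other probes, each with r over 0.9 across the 12 arrays, and 22 of these 35 were among the 34 rises. Against control siRNA, 0 of the 35 rose with APJ siRNA and 1 with both. Their median intensity (log2) was 12.82, 9.56 and 11.73 on APJ siRNA arrays 1, 2 and 3 and 12.86, 11.21 and 9.78 on the double knockdown arrays, against 8.22, 9.59 and 7.65 on the control arrays and 8.07, 8.99 and 9.50 on the apelin siRNA arrays. The split of 34 and 52 became 39 and 35 with cyclic loess and 53 and 53 in the second deposited table, and the count of 86 became 46 with no filter on dim probes. It was 37 without APJ siRNA array 3, 28 and 18 without apelin siRNA arrays 1 and 2, 21, 27 and 1.3e+02 (rounded) without double knockdown arrays 1, 2 and 3, and 17, 43 and 13 without control arrays 1, 2 and 3. These 4 calls were lost without 8 to 10 of the 12 arrays.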

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

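Tests of the probes undetected on the control arrays, of additive effects, of a shift of the control arrays and of position on the chip were chosen after the values they measure, or closely related ones, had been seen. So were the regroupings that kept the other siRNA in place. The simulation of shared controls and the counts over other splits of the arrays were set before.

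A test of whether the effect of apelin siRNA differed with and without APJ siRNA called 7 probes, of which 3 were detected on all 12 arrays and 5 belong to the 10 probes weighed next. The interaction was 2.38 for ILMN_3167074, 2.24 for ILMN_3168216 and -2.58 for ILMN_3168339, the last a fitted value that rests on background levels, since 3 of the 4 groups left this probe undetected on every array. ILMN_3168216 was detected on 1 of 3 arrays in each knockdown group. Of 100 random splits of the 12 arrays, 2 gave as many calls, the real split included, and the other called 43, but such splits mix the effects of each siRNA into the spread. When residuals of a fit without interaction were exchanged between arrays, again 2 of 100 gave as many, a share with a 95% exact interval of 0.243% to 7.04%, and the highest other called 55, so chance is not excluded at 0.05. Counts several times the real one point to structure among the arrays.

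For the 10 probes changed in the same direction in all 3 comparisons with control siRNA, additive effects of the 2 knockdowns alone were weighed by the interaction. Additive levels under the lowest detected intensity were raised to it. Over 8 of the 10 the median interaction was 1.38 (log2) against the change, with quartiles of 0.85 and 1.64. A choice of probes by their difference from the control arrays favours this sign, so the median does not decide against additive effects for each probe. Of the 8, the limma interaction was called for ILMN_3167074, ILMN_3167175 and ILMN_3168884, and the others had adjusted p of 0.0681 to 0.122. Additive effects also stay open for ILMN_3167801 and ILMN_3168216, 2 probes whose additive and observed levels both lay under the lowest detected intensity. Chance values shared through simulated control arrays gave as many probes in 0 of 100 simulations, which drew probes independently. That argues against such chance values for independent probes only, and chance variation shared by many probes stays open. A shift of the control siRNA arrays alone would give an interaction of the size of the change and knockdown groups at 1 level, and 2 of the 10 probes, ILMN_3168187 and ILMN_3168884, differed among the knockdown groups (limma F test, adjusted p = 0.0267 and 0.0256, adjusted over the list alone). That test took its spread from all 12 arrays. For these 2 probes the control SD was 0.07 and 0.05, against up to 0.51 and 0.34 in a knockdown group. Their adjusted p may therefore be too small, and whether a shift of the controls gave all of their change is not settled. For the other 8 a missed threshold does not show equal levels. The study had 1 control siRNA, so a response to it, and a biological response common to loss of ligand and of receptor, stay open as hypotheses.

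For the 65 probes undetected on the control arrays and bright on some knockdown arrays, a first test, the share of their excess intensity in 1 component (84.0%, 74.3% to 90.8% over 2000 bootstraps), decided nothing, and the test by pairs replaced it. With 1 admixed RNA source the excess would be proportional between the 4 arrays that detected at least 40 of them. A source common to APJ siRNA array 1 and the others is argued against by Spearman rho of -0.016 to at most 0.181 (-0.0777 to 0.423), but 1 common to APJ siRNA array 3 and apelin siRNA arrays 2 and 3 stays open, with rho of 0.662 (0.49 to 0.791), 0.68 and 0.705; several sources are not excluded. Arrays on nearby sections were not more alike, with a rho of 0.238 between distance and correlation (0.165 to 0.3 with each array left out). Neighbouring sections of these arrays held different siRNA groups, so a group difference can hide a likeness of neighbours, and position stays open. A scaling factor of 1 per array is argued against by 5 of 9 arrays. On these, such probes, chosen for each array from the other arrays, moved 0.55 to 3.43 (log2) away from the detected probes. The siRNA group stays open, since 9 of 100 regroupings of the 9 arrays gave as large a share of variance between groups as the observed 0.439, and the highest other gave 0.671.

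For the 34 probes changed by apelin siRNA averaged over APJ siRNA, a linear gradient along the chip was weighed by slopes within groups. The effect and that predicted by these slopes had an r of -0.39 (-0.523 to -0.032 with each array left out), which does not favour a gradient. Within each group the section rose in step with the replicate number. A trend with replicate number could therefore hide a gradient, which is not excluded. With the section as a covariate all 34 kept their sign and the median effect went from 0.92 to 1.03, and the calls ended because the median standard error went from 0.16 to 0.34. A step between the 2 sides of the chip, sections A to F and G to L, cannot be told apart from apelin siRNA, since 0 groups had arrays on both sides. A biological effect of apelin siRNA therefore may account for these probes and remains untested against that step.

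Against control siRNA, the real split called 28 probes for apelin siRNA, 67 for APJ siRNA and 28 for both, where the highest of the other splits called 0 each time. For apelin siRNA against APJ siRNA it called 80, and the highest other split 40. In each of these comparisons the real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05. For apelin siRNA averaged over APJ siRNA 2 of 100 splits called as many as the real 34, the highest other 72, and for APJ siRNA averaged over apelin siRNA 2 of 100 called as many as the real 86, the highest other 92. Such splits mix the effect of the other siRNA into the spread. With splits inside each level of the other siRNA, 2 of 100 again called as many for each, and the highest others called 92 for apelin siRNA and 137 for APJ siRNA. For the interaction, the same share of 2 of 100 had an exact interval of 0.243% to 7.04%. That interval belongs to the interaction alone. For the averaged comparisons the share of 2 of 100 lies under 0.05, but no interval was computed for it, so chance is not called excluded. Single splits with more calls than the real one point to structure among the arrays. Of all splits, 56.7% lie at least as close to the real one as the split with 72 calls. For the split of all 12 arrays with 92 calls for APJ siRNA averaged, and that with 43 for the interaction, it was 8.01%. Each kept 10 of 12 arrays on their real side, so these 2 counts may carry part of the real grouping.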

How the results depend on the processing

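Weights per siRNA group and the fit without the 65 probes undetected on the control arrays were chosen after the data were seen. Counts of changed probes are given in the order apelin, APJ and both siRNAs against control siRNA, apelin against APJ siRNA, the interaction, and apelin and APJ siRNA averaged, where they were 28, 67, 28, 80, 7, 34 and 86. Apart from those with the block, counts within 1.5 times are left out below, and the cause of a move was not tested unless one is given.

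With the section as a linear covariate the first 6 counts became 1, 31, 4, 7, 38 and 0. The replicate block gave 25, 36, 19, 49, 2, 27 and 32. Deviations of the 18 pairs with 1 number correlated at -0.465 to 0.628, 5 of them over 0.1. Their mean was -0.0386, against 0.019 for pairs with different numbers, and 3 of 12 arrays lay closest to their own number. The numbers thus did not pair the arrays as a set, but a pairing of some arrays is not ruled out. With only the compared groups the count was 44 for apelin siRNA, 19 for APJ siRNA and 2 between them. The full fit shares 1 spread, whereas the median probe SD ran from 0.16 with control siRNA to 0.47 with APJ siRNA. An equal spread therefore did not hold between the groups. Weights per group gave 60 for apelin siRNA, 51 for both, 38 between the single knockdowns and 11 for the interaction, with weights of 2.99 for control arrays and 0.471 to 0.852 for the others. A trended, robust spread gave 102 for APJ siRNA and 11 for the interaction. The interaction also became 12 with no background correction, 37 with median scaling, 31 with cyclic loess, 4 in the second deposited table, 3 with no filter and 1 with detection on all 12 arrays. Cyclic loess gave 62 for apelin siRNA averaged, and no filter 46 for APJ siRNA averaged. Without the 65 probes every count stayed within 1.5 times.

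With each array left out in turn the counts ran from 10 to 75, 11 to 188, 7 to 32, 23 to 107, 0 to 122, 15 to 56 and 13 to 1.3e+02 (rounded). A group left with 2 arrays shared the spread of the others.

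The correlation across probes of apelin and APJ siRNA became 0.292 among probes detected on all 12 arrays, and that of apelin siRNA and the double knockdown 0.523. For comparisons without shared arrays, that of apelin siRNA without and with APJ siRNA became -0.101 with no background correction and turned to 0.237 with detection on all 12 arrays, where dim probes are left out, and that of APJ siRNA became 0.577. With each array left out the 5 correlations ran from 0.387 to 0.63, 0.27 to 0.439, 0.478 to 0.744, -0.517 to -0.228 and -0.1 to 0.32. The last turned to -0.0701 without APJ siRNA array 1, -0.0546 without double knockdown array 1 and -0.1 without apelin siRNA array 1.

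Other scalings moved the median change of all probes from -0.04 to at most 0.09 for apelin siRNA, from -0.18 to 0.08 for APJ siRNA and from -0.09 to 0.03 for both, and changes are relative to it. Probes near background give bounds only. No named probe turned its direction. The 10 shared probes kept 8 to 10 of their number under every background, scaling and filter setting, 5 with the block and 1 with the section, and 4 without control array 1, 2 or 3 or double knockdown array 1, 5 without APJ siRNA array 3 or apelin siRNA array 2 and 6 without APJ siRNA array 1. The fit restricted to probes with a microRNA name, and the list tests, were not run because probe names were not used here.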

Other observations

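ILMN_3167951 was higher on the arrays with apelin siRNA, whether or not APJ was also knocked down. Those arrays all lay on sections G to L, so apelin siRNA and the side of the chip cannot be told apart. ILMN_3167951 rose by 3.12 (log2) against control siRNA and by 3.29 in the double knockdown against APJ siRNA. The interaction was 0.18 (adjusted p = 0.909), which does not show equal responses, and the probe lay at 8.95 ± 0.52 with APJ siRNA alone. ILMN_3168339 was detected with APJ siRNA alone, at 7.65 ± 0.38, and on no array of the other groups. ILMN_3168669 and ILMN_3166999 lay at 8.69 ± 1.40 and 8.50 ± 0.84 with APJ siRNA, and at 7.29 ± 1.22 and 7.35 ± 1.32 with apelin siRNA, where each was detected on 2 of 3 arrays. Both were undetected on all arrays of the control and double knockdown groups.

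Of the 12 arrays, 6 correlated best across probes with an array of their own group, and of the 9 knockdown arrays 3 did. An exchange of labels or extracts was not tested and is not excluded. APJ siRNA array 1 was closest to double knockdown array 1 (r = 0.972), APJ siRNA array 2 to double knockdown array 2 (0.959), APJ siRNA array 3 to apelin siRNA array 3 (0.927), and apelin siRNA array 1 to double knockdown array 3 (0.984). The closest array lay on the same side of the chip, sections A to F or G to L, for 8 of 12. The siRNA groups held 55.8% of the variance over probes, where groups without effect would hold 27.3%.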
